A study of Mus musculus with 16 samples.

How the data were processed

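Expression was measured in bone marrow-derived macrophages of male wildtype C57BL/6J mice on Illumina mouse bead arrays with 25697 probes. The 16 arrays fell into 8 groups of 2, from 2 experiments with 3 h and 6 h of LPS and 4 treatments each: vehicle, 1 µM Dex, vehicle then LPS, and Dex then LPS. Groups and times were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and cleaned on columns with DNase treatment in the 3 h experiment, and extracted on columns with DNase treatment in the 6 h experiment. Quality was checked on a Bioanalyser and biotin-labelled cRNA was made with an Ambion amplification kit. The submitters' processing notes name GenomeStudio, with no version given.

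The deposited data held 4 tables. Per the file headers, the unnormalized 3 h table and the unnormalized 6 h table give for each array a signal, which is an intensity on a linear scale, and a detection p-value. Their lowest values show that background was still in the signal. Another deposited table gives the intensity and detection p-value of 6 h samples after what its headers call cubic spline normalization by the authors. There, 11345 to 11857 probes were detected per array, and the table was used only as an alternative because its ranks differ from those of the unnormalized table. The last is the authors' processed value table over all 16 arrays. Its 3 h columns hold intensity values whose order was that of the unnormalized 3 h table (rank correlation 1 for all 8 arrays). Their medians were 167.0235 and 167.0537 for the arrays labelled unstimulated, 167.049 and 166.9836 for Dex, 167.0574 on both for LPS, and 167.0574 and 167.0666 for Dex plus LPS. Its 6 h columns hold values centred per probe that behaved as log2 differences, as set against the authors' unnormalized 6 h table (slope 0.957 to 0.988, Pearson correlation across probes 0.973 to 0.988). Their column medians were 0.163 and 0.106 for the unstimulated arrays, -0.0978 and -0.0893 for Dex, 0.0458 and 0.0170 for LPS, and -0.0123 and -0.197 for Dex plus LPS, and 4003 probes were empty. Scale, centring and direction of both parts were found by these comparisons and none of them stays unknown, but the log base of the 6 h part rests on the slope alone, and the normalization behind it is not given in the sources used here. In the 3 h unnormalized table the column names show the group but not which array is which sample, so those columns were used as replicates of their group and numbered by their letters. Its detection p columns carry no array name, and each was read as that of the signal column opening its block, with which it never rose. The 32 columns of bead numbers and bead standard errors were not used here.

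Background was corrected with the normexp model of limma (version 3.58.1, R version 4.3.3), with the negative control level inferred from the detection p-values and an offset of 16, then values were quantile normalized within each experiment and taken as log2. Levels were set across experiments, after normalizing all 16 arrays together, only to check labels. A probe was used where its detection p was under 0.05 on both arrays of at least 1 group of the experiment, which kept 12282 probes in either experiment. Genes were named through the platform annotation. There 23846 probes had 1 symbol, 0 had several and 1851 were not listed and stay unnamed here, 800 of them among the detected probes. Of the symbols 23839 were matched to RefSeq genes by Entrez identifier or accession and updated where they had changed. For a gene with several detected probes (2231 genes) the probe with the highest mean over all 16 arrays stood for the gene, and no gene had probes called in opposite directions. A gene was tested in an experiment where that probe was detected. This left 8032 genes at 3 h, 7791 at 6 h and 7458 in both. Of the 25697 probes 43.9% to 46.4% were detected per array at 3 h and 40.5% to 43.9% at 6 h, and the number of arrays limits the precision.

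Each comparison was fitted with limma's lmFit and eBayes on the 8 arrays of an experiment with 1 mean per group, and p-values were adjusted by Benjamini-Hochberg. A gene was called at an adjusted p under 0.05 and at least 2-fold. The comparisons were LPS against unstimulated, Dex against unstimulated, Dex plus LPS against LPS, and the difference of the 2 Dex effects. A second fit used the mean of each pair of technical replicates with experiment as a block, so that the 2 experiments were the only repeats. Differences between the experiments' responses were tested on all 16 arrays with 8 group means, on values normalized within each experiment. A gene had only a bound in a group where none of its probes was above background on any array of the group, or where its probe was saturated on all of them (at least 80% of the array's highest signal). The fold is then given as "at least" and sets the brighter group's mean of normalized log2 values against the dimmer group's mean of, per array, the higher of the lowest detected value and the gene's own. For the interaction and the differences between experiments, sizes are given only of genes measured in all groups used.

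Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over 120 tests, and with fry. Of 414 list members 365 were named on the array. The 18 lists were inflammatory cytokines, chemokines, inflammatory enzymes and effectors, interferon-stimulated genes, NF-kB regulators, immediate-early genes, known glucocorticoid-induced genes, the glucocorticoid receptor and cofactors, phagocytosis, alternative activation, MHC class II, MHC class I, Toll-like receptor pathway, cell cycle, sterol synthesis, glycolysis, lysosome and macrophage identity. The 7 lists of other cell types held markers of neutrophils, dendritic cells, T and NK cells, B cells, fibroblasts, erythroid cells and mast cells. Lists with under 3 measured members were counted but not tested. With an estimated correlation (adjusted p = 0.048 in each case) the camera calls that held were those of the enzymes and of the NF-kB regulators for LPS at 6 h and of the interferon-stimulated genes for Dex at 6 h and for Dex with LPS at 3 h and 6 h, and no other held.

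The genes named in the text were fixed by rule. They are, per comparison, the 12 raised and 12 lowered genes with the largest smaller change among those called in both experiments, 6 each way for the interaction and for the difference of the LPS response between experiments, and up to 4 called members of each list, or members needed to describe what did not change. A fixed set of glucocorticoid and inflammatory genes was always reported. Further genes called in the 6 h experiment alone (for LPS and for Dex alone, the 12 with the largest change each way among those measured on both sides, and 8 each way for the interaction) were added after the data were examined, because few calls were shared where arrays of doubted labels are used. The groups, tests, lists, naming rule and alternative settings were fixed before the data were examined. The design was kept as written, except that slide as a block was planned but not run.

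The alternatives were no background correction (values under 1 set to 1), median scaling, quantile normalization over all 16 arrays, the authors' processed values, the authors' cubic spline table, no filter on dim probes, a detection p under 0.01, the mean of all probes of a gene, no fold minimum, at least 1.5-fold, a variance prior with trend and robust fitting, the replicate number as a block, other selections of LPS-induced genes and leaving out each array in turn. The code was tested on simulated arrays in which 68 genes were changed 2-fold, 66 genes 3-fold and 66 genes 4-fold. For the LPS response at 3 h, over 8032 genes, 45.6%, 89.4% and 98.5% of them were recovered with 2 false calls. At 6 h, over 7791 genes, the shares were 47.1%, 89.4% and 92.4% with 4 false calls. For Dex with LPS in the fit over both experiments, over 7458 genes, they were 1.47%, 47.0% and 66.7% with 4 false calls. A gene changed exactly 2-fold is called only where its estimate reaches the 2-fold minimum. Of these genes 86.8% at 3 h, 64.7% at 6 h and 5.88% in the fit over both experiments passed the adjusted p. A simulated list of 20 genes raised 2-fold among 7791 had a camera p of 1.24e-47, and the smallest p of 20 other lists was 0.145. The simulated noise was independent between genes, so this cannot show how camera at the preset correlation fares with correlated genes.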

Results

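Gene expression was measured on Illumina bead arrays in macrophages grown from the bone marrow of male wildtype C57BL/6J mice. Cells received ethanol as vehicle or 1 µM dexamethasone (Dex), a synthetic ligand of the glucocorticoid receptor, overnight. They were then left unstimulated or given lipopolysaccharide (LPS), a bacterial cell wall component sensed through Toll-like receptor 4. The series held 2 experiments, with 3 h and 6 h of LPS, and each had 4 treatments with 2 arrays per treatment, 16 arrays in all. The labels call the arrays of a group technical replicates, so the p-values below measure only the spread between arrays and not that between cultures. Of 25697 probes, 11273 to 11921 were detected per array in the 3 h experiment and 10407 to 11281 in the 6 h experiment. The median signal was 164 to 172 and 154 to 189, and the median residual SD between arrays of a group was 0.113 and 0.202 on the log2 scale. The number of arrays limits the precision of every value. All changes are log2 differences ± SE with n = 2 arrays per group unless a fold is named, and a gene was called at an adjusted p under 0.05 and at least 2-fold.

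The levels of LPS-induced cytokines went against some labels of the 3 h experiment. Tnf, which encodes tumour necrosis factor, had a signal of 1890 ± 403 (SD, n = 2) on the 6 h unstimulated arrays and 56064 ± 1307 on the 6 h LPS arrays. It was at 62658 ± 177 on the 3 h arrays labelled unstimulated, 62118 ± 1035 on those labelled Dex and 62694 ± 501 on those labelled LPS, all in the saturated range. Il6, encoding interleukin 6, was below the detection threshold on the 6 h unstimulated arrays (159 ± 12.2) and reached 3997 ± 175 with LPS. Its signal was 1941 ± 15.6 on the 3 h arrays labelled unstimulated. Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce, was at 251 ± 46.4 on the 6 h unstimulated arrays and 2989 ± 223 on the 6 h Dex arrays. On the 3 h arrays it was at 239 ± 12.1 where labelled Dex, 239 ± 12.9 where labelled unstimulated and 1873 ± 155 where labelled Dex plus LPS. Over the 653 genes that LPS raised in the 6 h experiment, with the 6 h unstimulated arrays set at 0 and the 6 h LPS arrays at 1, the 3 h arrays labelled unstimulated had a mean position of 0.826. Those labelled Dex stood at 0.824, those labelled LPS at 0.837 and those labelled Dex plus LPS at 0.685. Levels were set across experiments only for this check. The labels were kept as given, and every 3 h direction below that uses the arrays labelled unstimulated or Dex rests on labels that these levels go against.

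**Figure D1:**
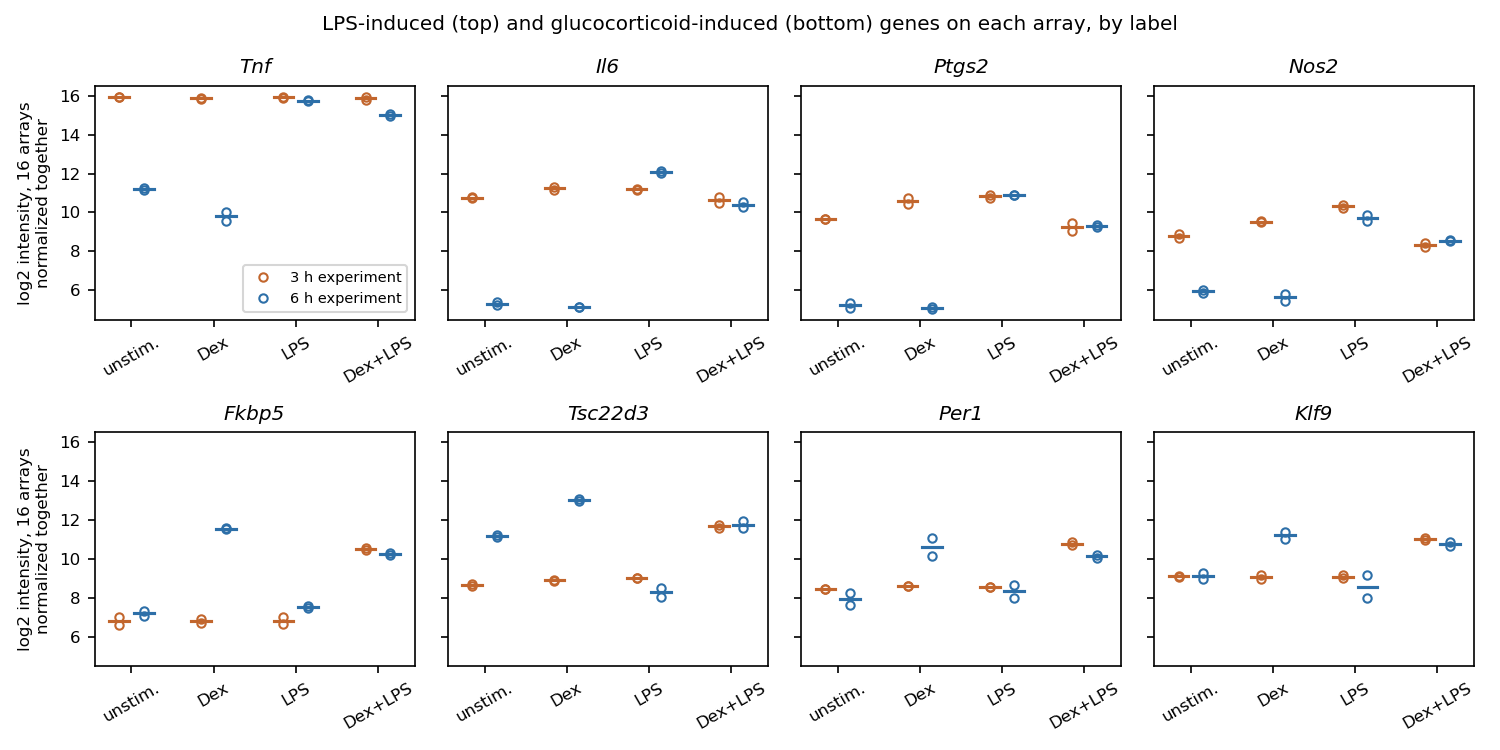
Normalized log2 intensity of 4 LPS-induced genes (Tnf, Il6, Ptgs2, Nos2) and 4 glucocorticoid-induced genes (Fkbp5, Tsc22d3, Per1, Klf9) on the 16 arrays by labelled treatment, with circles for arrays, lines for group means, orange for the 3 h and blue for the 6 h experiment. On the 3 h arrays labelled unstimulated the Tnf signal was 62658, against 1890 on the 6 h unstimulated arrays.

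The first comparison asked which genes LPS changed. In the 6 h experiment LPS raised 653 and lowered 679 of 7791 genes. The neutrophil-attracting chemokines Cxcl1 and Cxcl2 rose by 7.16 ± 0.30 (143-fold, adjusted p = 1.6e-07) and 7.04 ± 0.23 (132-fold, adjusted p = 3.65e-08), and the cytokine gene Il1a by 6.61 ± 0.27 (97.5-fold). Il6 was at least 53.9-fold higher, Il1b at least 40.7-fold, Tnf at least 24.9-fold and the prostaglandin synthase gene Ptgs2 at least 23.7-fold. St6gal1, a sialyltransferase gene, fell by 4.56 on the log2 scale (SE 0.18, 23.6-fold, adjusted p = 1.51e-07), and the lymphoid chemokine receptor gene Cxcr4 was at least 8.75-fold lower. Here and below "at least" marks a bound, since the gene was not above background on any array of the dimmer group or saturated on every array of the brighter one.

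By group, 13 of 15 measured inflammatory cytokine genes rose in the 6 h experiment and none fell (camera adjusted p = 4.79e-15, and adjusted p = 0.0553 with an estimated correlation). Il12a, for a subunit of interleukin 12, was at least 27.6-fold higher and Il27 at least 21.2-fold. Among chemokine genes 9 of 15 rose, with Cxcl10 at least 14.7-fold and Ccl3 at least 10.4-fold higher (camera adjusted p = 8.82e-07, and adjusted p = 0.0671 with an estimated correlation). Of 17 inflammatory enzymes and effectors 10 rose, among them Slc7a2 (3.98 ± 0.16), a cationic amino acid transporter gene, Serpinb2 (3.97 ± 0.21) and the prostaglandin E synthase gene Ptges (3.77 ± 0.24), and the test held with an estimated correlation (adjusted p = 4.31e-10, and adjusted p = 0.048 with an estimated correlation). Interferon-stimulated genes rose in 17 of 32 cases, with Gbp5 at 4.73 ± 0.19, Ifnb1, the interferon beta gene, at 3.95 ± 0.19 and Mx1, an antiviral GTPase gene, at 2.66 ± 0.20 (adjusted p = 2.23e-12, and adjusted p = 0.0553 with an estimated correlation). NF-kB subunits and feedback regulators rose in 15 of 22 cases, with Dusp2 at least 9.17-fold, Nfkbiz 3.01 ± 0.27 and Socs1 at least 5.06-fold (adjusted p = 5.06e-13, and adjusted p = 0.048 with an estimated correlation). Immediate-early and AP-1 genes had 5 of 12 members higher, led by Egr1 (3.29 ± 0.23), and Fos lower (adjusted p = 0.0275, and adjusted p = 0.194 with an estimated correlation). Phagocytosis and efferocytosis genes went both ways, with 4 of 18 higher, among them Itgav (1.95 ± 0.30) and Fcgr2b (1.79 ± 0.18), and 4 lower, among them Itgb5 (-1.41 ± 0.23). Of 8 genes of alternative activation, Tgm2 rose and Clec7a (-1.40 ± 0.17), Cd200r1 and Clec10a fell. Of 11 genes of MHC class II and co-stimulation, Cd40 (3.45 ± 0.19) and Cd83 rose and H2-DMa fell. Of 19 known glucocorticoid-induced genes, Tsc22d3 (-2.87 ± 0.20), which encodes a leucine zipper protein that restrains NF-kB and AP-1, and Rgs2 fell. For all of these lists the counts adjusted over the list alone were the same.

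In the 3 h experiment 168 of 8032 genes were higher and 67 lower on the arrays labelled LPS than on those labelled unstimulated. None of 17 cytokine genes and none of 14 chemokine genes was called with limma, over all genes or adjusted over the list alone (9 and 6 at an unadjusted p under 0.05). Of these, 2 cytokine genes (Il1b and Tnf) and 5 chemokine genes (Ccl3, Ccl4, Ccl5, Cxcl1 and Cxcl10) were saturated in both groups and could show no change. Nos2, the inducible nitric oxide synthase gene, differed by 1.53 ± 0.12 and Ptgs2 by 1.17 ± 0.17, while Il6 differed by 0.44 ± 0.12 (adjusted p = 0.0315, under 2-fold). Socs1, the only called member of 22 NF-kB regulators, went the other way than at 6 h (-1.23 ± 0.14). Of the 3 h calls tested in both experiments, 19 genes were higher in both, where independent lists would share 11.7, and Trerf1, Tarsl2, Mfng and Sergef were lower in both, 4 genes where they would share 5.28. Called in opposite directions were 13 genes higher at 3 h and lower at 6 h and 6 lower at 3 h and higher at 6 h. Each of the 4 shared lowered genes lost its 3 h call without 1 or another of the LPS and unstimulated arrays, as Mfng did without LPS replicate 1 or unstimulated replicate 2 (-0.79 to -0.74). Among the shared genes were Itga5, an integrin subunit gene (1.73 ± 0.09 at 3 h), Phlda1 (1.51 ± 0.09, and 4.51 ± 0.47 at 6 h), Nlrp3, an inflammasome sensor gene (1.41 ± 0.10, and at least 2.03-fold), Malt1 (1.25 ± 0.10 and 2.63 ± 0.31) and Src (1.25 ± 0.07 and 1.87 ± 0.41). The correlation of the changes across genes was 0.0753, and genes are not independent replicates. The difference between the experiments, tested on all 16 arrays, passed for 1570 of 7458 genes (726 more positive and 844 more negative at 6 h), and time of LPS and experiment cannot be told apart. It uses the 3 h arrays of doubted labels, so it does not measure how the LPS response changed with time. A fit on the treatment means with experiment as a block called 0 genes with limma (691 at an unadjusted p under 0.05). It averages the 6 h response with that between 3 h arrays of doubted labels, so it cannot show whether the 6 h response repeats. With median scaling in place of quantile normalization the median change of all genes moved by 0.171 at 3 h and 0.139 at 6 h, and the calls became 266 higher and 26 lower at 3 h (91.1% higher, against 71.5%) and 845 higher and 481 lower at 6 h (63.7%, against 49.0%). In the authors' processed values they were 73 and 16 at 3 h (82.0%) and 509 and 272 at 6 h (65.2%).

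The second comparison asked what Dex did without LPS. In the 6 h experiment it raised 126 and lowered 147 of 7791 genes. Fkbp5 rose by 4.26 ± 0.17 (19.2-fold, adjusted p = 1.43e-06), the circadian regulator gene Per1 by 2.64 ± 0.32 (6.22-fold), F13a1, for the A subunit of coagulation factor XIII, by 2.85 ± 0.22 and Klhl6 by 2.58 ± 0.16. Egr2, an immediate-early transcription factor gene, fell by 2.78 on the log2 scale (SE 0.18, adjusted p = 5.2e-05). The interferon-induced chemokine gene Cxcl10 (-2.67 ± 0.26) and the cell cycle inhibitor gene Cdkn1c (-2.56 ± 0.20) fell too.

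Of 19 known glucocorticoid-induced genes 8 rose in the 6 h experiment (9 adjusted over the list alone), and Rgs2 fell. Il1r2, the decoy receptor of interleukin 1, was at least 3.53-fold higher, Klf9 rose by 2.10 ± 0.32, Tsc22d3 by 1.86 ± 0.20, Mertk, a receptor for apoptotic cells, by 1.78 ± 0.17 and the MAP kinase phosphatase gene Dusp1 by 1.57 ± 0.17. The list's camera adjusted p was 1.06e-04, and adjusted p = 0.104 with an estimated correlation. Interferon-stimulated genes fell in 11 of 32 cases, 11 also when adjusted over the list alone, with Rsad2 at -1.70 ± 0.16, Oasl1 at -1.70 ± 0.17, Isg15 at -1.59 ± 0.21 and Mx1 at -1.55 ± 0.20 (camera adjusted p = 9.37e-15, and adjusted p = 0.048 with an estimated correlation). Of 15 cytokine genes Il1a (-1.88 ± 0.27), Il1b (-1.67 ± 0.16) and Tnf (-1.41 ± 0.19) fell (adjusted p = 0.0374, and adjusted p = 0.324 with an estimated correlation). Of 15 chemokine genes Cxcl10 fell and Ccl6 (1.22 ± 0.19) and Ccl9 (1.07 ± 0.20) rose (adjusted p = 0.172). Among the enzymes and effectors the neutrophil gelatinase-associated lipocalin gene Lcn2 rose (1.70 ± 0.20), and Mmp13 (-1.78 ± 0.21), a collagenase gene, Serpinb2 and Mmp9 fell (adjusted p = 0.0615). Phagocytosis and efferocytosis genes had 4 of 18 members higher, Mertk, C1qc (1.30 ± 0.26), Thbs1 and Stab1 (5 adjusted over the list alone), and Mfge8 lower (adjusted p = 0.0015, and adjusted p = 0.142 with an estimated correlation). Cd40 (-1.88 ± 0.19) and Cd86 (-1.17 ± 0.22), which give T cells co-stimulation, fell among 11 genes of their list (adjusted p = 0.00342, and adjusted p = 0.142 with an estimated correlation). Of 8 genes of alternative activation Chil3 rose (1.60 ± 0.23) and Clec7a, the receptor of fungal beta-glucan, fell (-1.74 ± 0.17), with 2 higher when adjusted over the list alone. Egr1 (-1.19 ± 0.23) fell beside Egr2 among 12 immediate-early genes, and of 22 NF-kB regulators Dusp1 rose and Il1rn (-1.38 ± 0.19) and Nfkbib fell.

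In the 3 h experiment 43 of 8032 genes were higher and 18 lower on the arrays labelled Dex than on those labelled unstimulated. None of 18 known glucocorticoid-induced genes was called with limma, over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05). Fkbp5 differed by 0.00 ± 0.18, Per1 by 0.15 ± 0.08 and Tsc22d3 by 0.25 ± 0.09. Calls shared with the 6 h experiment were Tmem176a (1.24 ± 0.18 and 1.56 ± 0.37) and Tbc1d22b (at least 1.84-fold and 1.25-fold) among the raised genes, where independent lists would share 0.622, and 0 among the lowered ones. Anln, named after its values were seen, was called in opposite directions, lower at 3 h and higher at 6 h. Tmem176a lost its 3 h call without unstimulated replicate 2 (0.97) and its 6 h call without any 1 of the 6 unstimulated, LPS and Dex plus LPS arrays (1.27 to 1.86). Tbc1d22b lost its 3 h call without any 1 of those 6 arrays and its 6 h call without unstimulated replicate 1. Though the labels give the same treatment in both experiments, the difference between them passed for 302 of 7458 genes. A fit on the treatment means with experiment as a block called 0 genes with limma (191 at an unadjusted p under 0.05). Since it takes in the 3 h arrays of doubted labels, it cannot show whether the 6 h response to Dex repeats. At 3 h 27 were higher without Dex replicate 1 and 6 lower without Dex replicate 2. Single arrays decided the 6 h counts too: without Dex replicate 1 they were 77 higher and 92 lower, and without Dex replicate 2 they were 283 and 321. With median scaling the median change of all genes moved by 0.284 at 6 h and 0.137 at 3 h, and the calls became 414 higher and 64 lower at 6 h (86.6% higher, against 46.2%) and 75 and 12 at 3 h (86.2%, against 70.5%).

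The third comparison, Dex plus LPS against LPS, addressed how the glucocorticoid receptor shapes Toll-like receptor 4 signalling, the topic named in the title of the series. It uses arrays whose labels the levels of LPS-induced and glucocorticoid-induced genes did not go against. With Dex 93 genes were higher and 183 lower at 3 h, and 103 higher and 192 lower at 6 h. Klhl6 rose by 3.08 ± 0.08 at 3 h and 3.27 ± 0.16 at 6 h (8.47-fold and 9.62-fold, adjusted p = 4.05e-05 and 7.44e-06), and Ptx3, for a secreted pattern recognition protein, by 3.30 ± 0.12 and 2.89 ± 0.17. Fkbp5 rose by 3.82 ± 0.18 and 2.70 ± 0.17, and Tsc22d3 by 2.67 ± 0.09 and 3.44 ± 0.20. Ifnb1 changed by -2.32 ± 0.09 and -4.02 ± 0.19 (5.01-fold and 16.2-fold lower, adjusted p = 5.2e-05 and 7.44e-06), and Ch25h, for the enzyme that makes 25-hydroxycholesterol, by -2.21 ± 0.08 and -2.11 ± 0.28. On the 6 h Dex plus LPS arrays the Ifnb1 signal was 200 ± 4.73 (SD), close to the 196 ± 37.4 of the 6 h unstimulated arrays. The size of its 6 h change therefore rests on a value near background.

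Of the genes tested in both experiments, 36 rose and 75 fell in both, where independent lists would share 1.18 and 4.02, and 0 were called in opposite directions. The 2 experiments share no array, and the correlation across genes was 0.587. Other genes raised in both were the sulfotransferase gene Sult1a1 (at least 9.13-fold and 4.04-fold), F13a1 (2.43 ± 0.08 and 2.72 ± 0.22), Adamtsl4 (3.05 ± 0.19, and at least 4.24-fold), the acute-phase genes Orm2 (3.37 ± 0.14 and 1.96 ± 0.19) and Hp (2.03 ± 0.09 and 2.19 ± 0.19), and Trem1, an amplifier of myeloid activation (1.82 ± 0.20 and 2.45 ± 0.20). Lowered in both were the transcription factor gene Pou3f1 (at least 6.68-fold lower at 3 h and -2.85 ± 0.20 at 6 h), Flrt2 (at least 4.80-fold lower, and -2.60 ± 0.20), Mycl (-2.11 ± 0.18 and -2.33 ± 0.16), the interleukin 1 receptor antagonist gene Il1rn (-2.13 ± 0.08 and -1.89 ± 0.19), Mmp13 (-1.73 ± 0.07 and -2.09 ± 0.21) and Ptgs2 (-1.57 ± 0.17 and -1.62 ± 0.17).

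**Figure D2:**
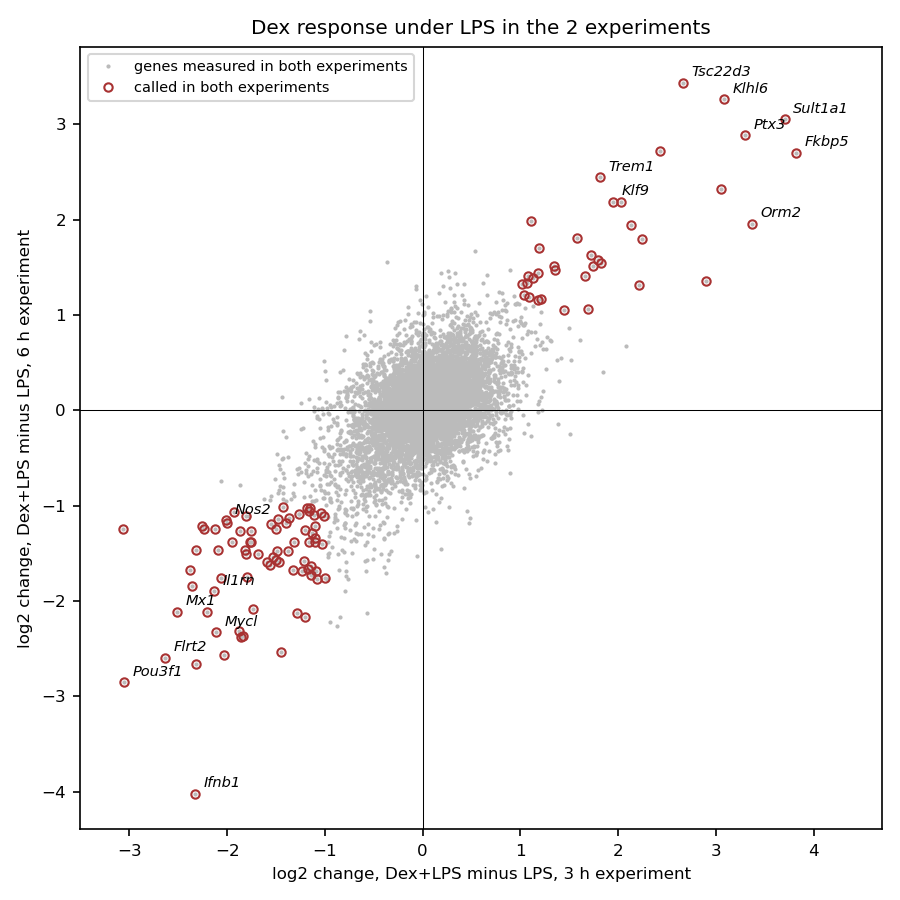
Log2 change of each gene between Dex plus LPS and LPS in the 3 h experiment (x axis) and the 6 h experiment (y axis), with red circles for genes called in the same direction in both. The 36 genes raised and 75 lowered in both lie in the upper right and lower left, and the correlation across genes was 0.587.

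Of 32 interferon-stimulated genes 15 fell with Dex at 3 h and 8 at 6 h, with the same counts adjusted over the list alone, and 0 rose. Beside Ifnb1 these held Mx1 (-2.51 ± 0.09 and -2.11 ± 0.20), Mx2 (-2.31 ± 0.07 and -1.47 ± 0.17) and Ifit2 (-2.26 ± 0.08 and -1.21 ± 0.27), of which Ifit2 lost its 6 h call without any 1 of the 4 LPS and Dex plus LPS arrays (-1.33 to -1.10). The camera adjusted p was 4.33e-19 at 3 h and 2.41e-16 at 6 h, and adjusted p = 0.048 with an estimated correlation at both. Of 15 cytokine genes 8 fell at 6 h (8 adjusted over the list alone), with Il23a at -1.77 ± 0.18, Il6 at -1.68 ± 0.18, Il12a at -1.29 ± 0.17 and Il1a at -1.28 ± 0.27 (adjusted p = 1.64e-10, and adjusted p = 0.0878 with an estimated correlation). At 3 h only Csf2 of 17 fell (-1.12 ± 0.29; adjusted p = 0.0453, and adjusted p = 0.266 with an estimated correlation), and Il6 differed by -0.58 ± 0.12. Tnf, Il1b and Cxcl10 were not called, but this says little of Dex, since their probes were saturated with LPS in both experiments. Tnf and Il1b, saturated with and without Dex at 3 h, have no fold there. At 6 h Tnf was at least 1.72-fold lower with Dex (adjusted p = 0.0354) and Il1b at least 1.32-fold, and Cxcl10 was at least 1.27-fold lower at 3 h and 1.64-fold at 6 h. Of 15 chemokine genes Ccl2 (-2.13 ± 0.23), Ccl7 (-2.13 ± 0.19), Ccl12 (-1.37 ± 0.18) and Cxcl3 fell at 6 h (adjusted p = 2.23e-04, and adjusted p = 0.107 with an estimated correlation). At 3 h Ccl7 alone of 14 was called (-1.29 ± 0.17), and Ccl2 differed by -0.57 ± 0.11. Saturated in both groups were 5 chemokine genes at 3 h and 3 at 6 h.

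Among the enzymes and effectors Nos2 (-2.01 ± 0.12 and -1.16 ± 0.19), Mmp13 and Ptgs2 fell at both times and Serpinb2 at 6 h, and Lcn2 rose at 3 h. Nos2 lost its 6 h call without LPS replicate 2 or either Dex plus LPS array (-1.17 to -1.01). The median of this list at 6 h was 0.0444 and its mean -0.378, which differ in sign (adjusted p = 0.0332, and adjusted p = 0.194 with an estimated correlation). Known glucocorticoid-induced genes rose in 7 of 18 cases at 3 h and 7 of 19 at 6 h, among them Per1 (2.25 ± 0.08 and 1.80 ± 0.32), Klf9 (1.95 ± 0.11 and 2.19 ± 0.32), Dusp1 (1.35 ± 0.07 and 1.51 ± 0.17) and Il1r2 (at least 3.51-fold and 1.99-fold). Sgk1 fell at 3 h and Zfp36, which destabilizes cytokine mRNAs, at 6 h (-1.49 ± 0.18). The adjusted p was 5.89e-04 and 0.00127, and adjusted p = 0.116 and 0.129 with an estimated correlation. Of 12 immediate-early genes Klf4 (-1.45 ± 0.16 and -2.53 ± 0.32), Egr2 (-1.20 ± 0.08 and -2.16 ± 0.18) and Atf3 (-1.76 ± 0.10 and -1.38 ± 0.19) fell at both times, and Jun rose at 3 h (1.84 ± 0.11; adjusted p = 0.0055 and 1.05e-04, and adjusted p = 0.172 and 0.104 with an estimated correlation). Of 11 genes of MHC class II and co-stimulation 2 fell at 3 h and 3 at 6 h, Cd83 at both (-1.32 ± 0.08 and -1.39 ± 0.20), Cd40 at 3 h, and Cd86 and Ciita at 6 h (adjusted p = 0.00154 and 0.0015, and adjusted p = 0.129 with an estimated correlation at both). Of 22 NF-kB regulators Dusp1 rose and Il1rn fell at both times. Chil3 rose (1.73 ± 0.09 and 1.63 ± 0.23) and Clec7a fell (-1.59 ± 0.20 and -1.59 ± 0.17) at both times among 8 genes of alternative activation. Of the phagocytosis genes Fcgr1 fell at both times, and Cd163 (at least 1.99-fold) and Fcgr3 (1.30 ± 0.10) rose at 3 h. The receptor gene Nr3c1 was not called (-0.40 ± 0.21 at 3 h, and at least 1.31-fold lower at 6 h). Its probe was near background, with a signal of 197 ± 9.08 (SD) with LPS and 183 ± 25.2 with Dex plus LPS at 3 h. At 6 h the signals were 204 ± 0.847 and 191 ± 5.11, so the probe says little of the receptor gene.

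A fit on the treatment means of both experiments called 0 genes with limma (422 at an unadjusted p under 0.05), with a spread that takes in the means of doubted labels. Restricted to the LPS and Dex plus LPS means, a choice made after the data were seen, it called 58 higher and 145 lower, among them all 36 and 75 genes called in both experiments. Without the 4 arrays of doubted labels the 3 h counts were 87 higher and 174 lower, of which 82 and 172 were shared with the full fit. Single arrays moved the 6 h counts to 45 higher and 107 lower (without Dex plus LPS replicate 1), 37 and 106 (without its replicate 2), 60 and 119 (without LPS replicate 1), and 54 and 112 (without its replicate 2). With median scaling the 6 h median of all genes moved by 0.142 and the calls became 204 higher and 152 lower (57.3% higher, against 34.9%), and in the authors' processed values they were 33 and 134 (19.8%).

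Whether the genes that LPS raised were those that Dex lowered was asked next. Of the 19 genes raised by LPS in both experiments, a selection that shares its LPS arrays with the test, 8 were lower with Dex at 3 h (42.1%, against 2.18% of other genes, Fisher's exact test, two-sided p = 3.8e-09) and 3 at 6 h (15.8%, against 2.43%, p = 0.0107). Nos2, Ptgs2 and Cd200, a ligand that restrains myeloid cells, were lowered at both times, Cd200 being named after its values were seen. The selection at 3 h rests on arrays of doubted labels, so the 639 genes raised by LPS in the 6 h experiment were also followed into the 3 h one, which shares no array with it. There 78 of them (12.2%) were lower with Dex, against 1.42% of other genes (Fisher's exact test, two-sided p = 9.35e-39), and 74.2% had a negative change, against 43.6%. Fisher's test treats genes as independent, which they are not, so its p-values here do not measure the spread between arrays or cultures. Within the 6 h experiment 119 of 653 LPS-raised genes were lower with Dex (18.2%, against 1.02%), but selection and test then share the LPS arrays. In 50 simulated sets of 6 h arrays without a Dex effect, a mean of 0.00294% and at most 0.147% were called lower. With no Dex effect on any gene few calls can pass the adjusted p, whether arrays are shared or not. These shares therefore do not measure what sharing adds to the calls. In the same sets a mean of 56.9% and at most 62.1% had a negative change, against 77.9% in the data. The simulated noise held only the spread between arrays and was independent between genes. It cannot show what a difference between cultures would give. Of 679 genes that LPS lowered at 6 h, 32 were higher with Dex (4.71%, against 0.998% of other genes), with the LPS arrays shared again. With no array shared, 13 of 646 were higher at 3 h (2.01%, against 1.08%) and 16 lower (2.48%, against 2.26%). Selection by the 3 h experiment alone gave the same 3 of 137 genes lower with Dex at 6 h (2.19%, against 2.47%).

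**Figure D3:**
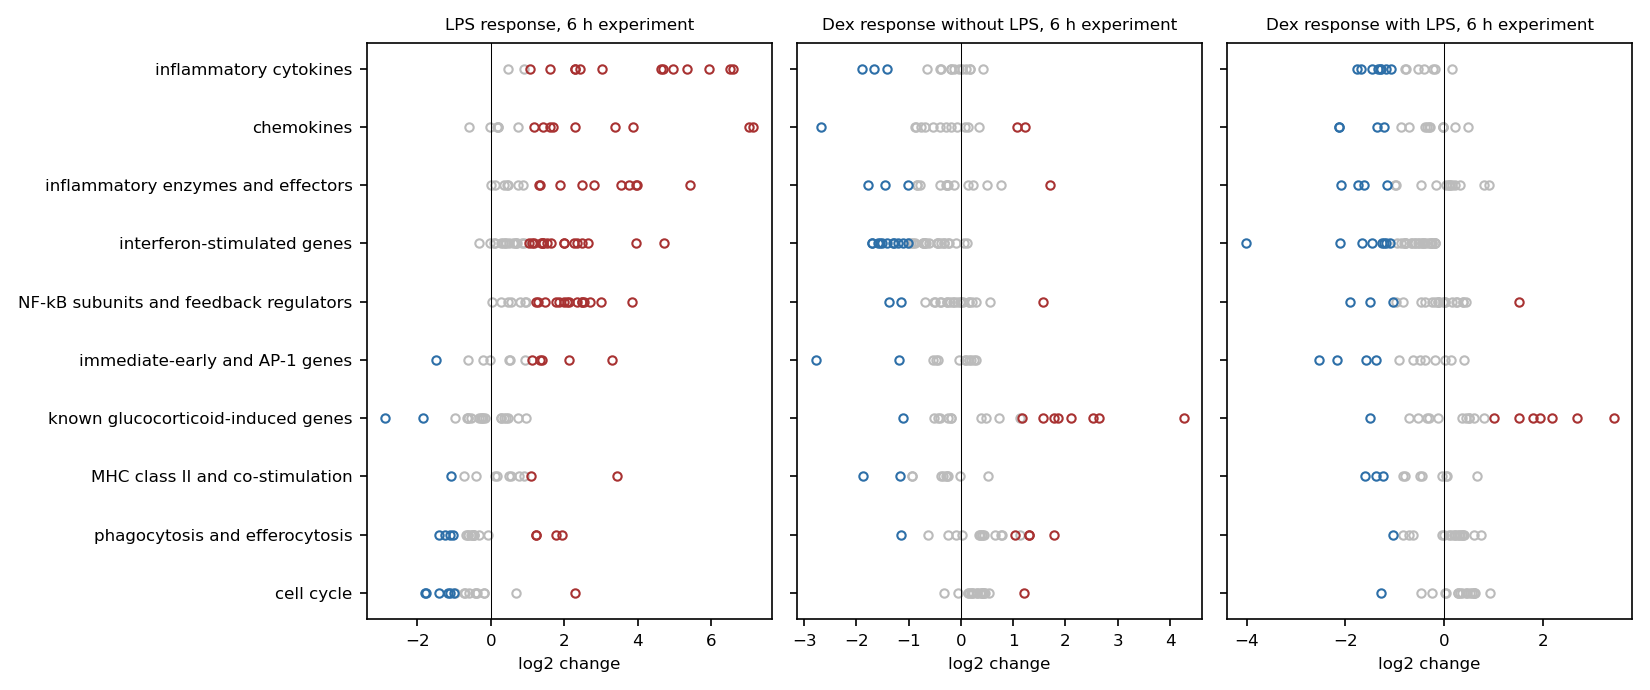
Log2 change of the measured members of 10 gene lists in the 6 h experiment, in panels for LPS, Dex without LPS and Dex with LPS, with red circles for genes called higher, blue for genes called lower and grey for genes not called. Of 15 cytokine genes 13 rose with LPS and 8 fell when Dex was added to LPS, and of 32 interferon-stimulated genes 17 rose with LPS, 11 fell with Dex alone and 8 fell with Dex added to LPS.

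Last, the effect of Dex with LPS was set against that without. In the 6 h experiment 29 genes rose and 51 fell in both settings, where independent lists would share 1.67 and 3.62, and Vcam1 and Kat2b were called in opposite directions. No array is shared, but both settings come from 1 fit with a common normalization and a common estimate of each gene's spread. The lists are therefore not independent, and the overlap is no repeat. The correlation across genes was 0.420. The effect itself differed for 44 genes at 6 h (15 more positive and 29 more negative with LPS). It differed for 709 genes at 3 h (268 and 441), which uses the arrays of doubted labels. Of these, 24 genes at 6 h and 601 at 3 h were measured in all 4 groups, and the others had only a bound in at least 1 group, so that the size of their difference is not known. Called at both times and measured in all groups were Tsc22d3 (2.42 ± 0.12 and 1.58 ± 0.29), Rgcc (1.16 ± 0.24 and 2.21 ± 0.26) and Klf4 (-1.76 ± 0.22 and -2.61 ± 0.45). Ptx3 (3.67 ± 0.17 at 3 h), Trem1 (2.32 ± 0.29), Mycl (-1.70 ± 0.25) and Ptgs2 (-2.49 ± 0.24) were called at both times too, but were not above background at 6 h without LPS, with or without Dex. Ifnb1 (-2.38 ± 0.13 at 3 h) was not above background on the 6 h Dex arrays. The 3 h values rest on arrays of doubted labels, where no known glucocorticoid-induced gene was called for Dex alone. A call at both times is therefore no repeat of the 6 h difference. Vcam1, an adhesion molecule gene named after its values were seen, had the largest 6 h difference among called genes (-3.95 ± 0.31), with 2.28 ± 0.22 for Dex alone and -1.67 ± 0.22 for Dex with LPS. The 6 h count was 14 without Dex replicate 1, 385 without Dex replicate 2, 3 and 6 without Dex plus LPS replicate 1 or 2, 4 and 7 without LPS replicate 1 or 2, and 9 and 16 without unstimulated replicate 1 or 2. A fit on the treatment means called 0 genes with limma (254 at an unadjusted p under 0.05), but it too uses the 3 h arrays of doubted labels and cannot decide whether the 6 h difference repeats.

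Markers of other cell types were followed in the same fits. Of 12 neutrophil genes 10 were measured, and Mmp8 was higher with Dex in the 6 h experiment (1.85 ± 0.31) and with Dex plus LPS against LPS at 3 h and 6 h (1.66 ± 0.29 and 1.41 ± 0.31), with a count at 3 h of 2 when adjusted over the list alone. Camp (-1.28 ± 0.19) and Ltf (-1.13 ± 0.21) fell with Dex alone at 6 h, so that neutrophil genes went both ways beside the rise of Lcn2 and Chil3. Ltf also fell with LPS at 6 h (-1.03 ± 0.21). Of the B cell genes 3 were measured and Blnk rose with LPS at 6 h (1.21 ± 0.21), beside the interferon and cytokine genes. Of the fibroblast and stromal genes 2 were measured and both rose with LPS at 6 h, Dcn by 1.40 ± 0.40, and Pdgfrb with no fold, since its bound was under 1. Of the mast cell and basophil genes 1 was measured at 3 h and 0 at 6 h, and none was called, and 0 dendritic, T and NK or erythroid genes passed the detection filter.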

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

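Of the tests in this part, the position of LPS-lowered genes and the level-matched gene sets were set down before their results were seen, and the other tests were chosen after.

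By the labels as given, the response to LPS differed between the 3 h and 6 h experiments for 1570 genes, that to Dex alone for 302 and that to Dex with LPS for 54 (22 more positive and 32 more negative at 6 h), each by a test of the difference on all 16 arrays. Of these, 1323, 261 and 49 were measured in all groups used, and the others had only a bound in at least 1 group. Of the 6 largest LPS differences each way, 6 h minus 3 h, those measured in all groups were Cxcl2 at 7.43 and Il1a at 6.86, and in the other direction Tpcn1 at -4.51 and St6gal1 at -4.27. Cxcl1, Mycl, Il12a and Il6 and, in the other direction, Cxcr4, Cnr2, Spry3 and Tmem154 passed the test too, but with a group not above background or saturated, so no size is given. The differences for LPS and for Dex alone use the 3 h arrays of doubted labels. On the LPS scale those labelled unstimulated stood at 0.826 and those labelled LPS at 0.837. At 3 h Cxcl2 and Il1a changed by -0.39 and -0.26, Tpcn1 by 1.11 and St6gal1 by -0.29. These differences therefore do not measure how a response changed with time. Of the genes named for Dex with LPS by the fixed rules, those whose effect of Dex with LPS differed were Fkbp5 at -1.12, Orm2 at -1.41, Ifnb1 at -1.69 (near background at 6 h with Dex plus LPS), Il6 at -1.10, Ccl2 at -1.56, Jun at -1.44, Psme2 at -1.28 and Il23a at -1.01. Genes named only for other comparisons are not listed here, and time of LPS and experiment cannot be told apart.

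The first pattern is that the 3 h arrays labelled unstimulated and Dex carried LPS-type levels. A swap of labels among the 8 arrays of the 3 h experiment is argued against because the lowest of the 8 stood at 0.682 on the scale from 6 h unstimulated (0) to 6 h LPS (1), so that no array had unstimulated levels. Brighter arrays or the normalization are argued against because the 679 genes that LPS lowered at 6 h were lowered on these 4 arrays too, at a mean position of 0.791 (0.782 to 0.795 on the 4 arrays, and 0.840 on the 3 h arrays labelled LPS). RNA of stimulated cells without Dex, by a wrong label or by the treatment itself, remains a candidate explanation, since in group means they stood at most 0.0135 below those labelled LPS, and over 126 Dex-raised genes those labelled Dex stood at 0.212 against 0.751 for Dex plus LPS. No biological explanation was tested. A basal difference of the cultures alone would leave a Dex response on the arrays labelled Dex. Over the 126 Dex-raised genes these stood at 0.212 (0.186 to 0.239), near the 0.182 of those labelled unstimulated. For the arrays labelled Dex this argues against a basal difference as the whole cause. For the arrays labelled unstimulated it stays open.

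The second pattern is that the table the authors call cubic spline normalized, which names the same 6 h samples, held an LPS response and no called Dex response. LPS raised 161 and lowered 43 of 8051 genes there, of which 124 and 33 were shared with the unnormalized 6 h table (12.5 and 3.93 for independent lists), while limma called 0 genes for Dex alone (744 at an unadjusted p under 0.05) and 0 for Dex with LPS (1559). For Dex with LPS 145 genes had an adjusted p under 0.05 but none reached 2-fold, and 69 of the 138 also tested in the unnormalized table had the same sign there. For Dex alone 0 had such an adjusted p. Normalization alone is argued against because the highest rank correlation of a sample between the tables was 0.858, and another order of columns because the highest of any pair was 0.859. Other arrays of the same treated cultures are argued against because 55.5% of 245 genes called for Dex with LPS had the same sign. What the table holds stays open, and no biological explanation was tested.

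The third pattern is that genes LPS raised were called lower with Dex more often than other genes. Shared LPS arrays are argued against as the whole cause because the share was 10.8 percentage points above that of other genes when no array was shared. A higher level of these genes is argued against because 12.2% were called lower, and the highest share among 1000 sets of other genes of matched level was 2.82% (mean 1.35%). That Dex restrains part of the LPS response may be a biological difference, as a hypothesis found and tested on the same data. Selection by the arrays of doubted labels gave 2.19% at 6 h.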

How the results depend on the processing

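The added fits on fewer arrays were chosen after the data were seen, and all other alternatives before. Of 545 recomputed counts and shares 434 stayed within 1.5 times the reported value and 111 did not, and a count or share has no sign to reverse. The 434 include 156 counts of the fit on both experiments that were 0 and stayed 0, which shows no stability; without them it was 278 of 389. The balance of calls did turn with median scaling, from 103 higher and 192 lower to 204 and 152 for Dex with LPS at 6 h, from 126 and 147 to 414 and 64 for Dex at 6 h and from 653 and 679 to 845 and 481 for LPS at 6 h. For LPS at 6 h it also turned without background correction (420 and 351) and in the authors' processed values (509 and 272). For single named genes 2887 of 3084 values kept their call and direction and 197 lost the call, and when 1 array was left out 2117 of 2248 kept it and 131 lost it. Only genes already called entered, so the 281 values at a 1.5-fold minimum and the 281 with no fold minimum were kept by construction. Without background correction 212 values kept the call and 69 lost it, and in the authors' processed values 212 kept it and 69 lost it. At 3 h these settings gave the same counts of higher, lower and interaction genes, so they are not separate checks there. Where a count moved the cause was not tested. With 2 arrays per group the lone array left in a group is assumed to vary like the other groups, and dim genes carry only bounds. Slide as a block was not run, since the column names give no slide, and values of single named genes in the cubic spline table, which holds other values, were not counted here.

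At a 1.5-fold minimum the counts of higher and lower genes were 476 and 583 (Dex with LPS, 3 h), 252 and 361 (6 h), 251 and 149 (Dex, 3 h), 251 and 280 (6 h), 569 and 539 (LPS, 3 h), and 1176 and 1507 (6 h), with 1853 for the 3 h interaction, 2666 for the LPS difference between experiments and 600 for the Dex difference. With no fold minimum they were 1364 and 1182, 252 and 361, 629 and 443, 251 and 280, 1317 and 1480, and 1264 and 1684, with 2609, 2835 and 602, and a share of LPS-induced genes lower with Dex of 65.4% at 3 h; more genes pass a looser threshold by construction. Without background correction they were 39 and 81, 35 and 103, 8 and 2, 61 and 69, 73 and 16, and 420 and 351, with interactions of 289 (3 h) and 72 (6 h) and differences of 912 and 146. The authors' processed values gave 39 and 81 (Dex with LPS, 3 h), 33 higher (6 h), 8 and 2 (Dex, 3 h), 59 and 69 (6 h), 73 and 16 (LPS, 3 h) and 272 lower (6 h), with interactions of 289 and 88, differences of 927 and 146 and a 3 h share of 71.4%. The authors' cubic spline table gave 0 and 0 for Dex with LPS at 6 h with limma (1559 at an unadjusted p under 0.05), 0 and 0 for Dex (744), an interaction of 0 (1009) and 161 and 43 for LPS; 145, 0 and 20 genes of the first 3 had an adjusted p under 0.05, and none of them reached 2-fold.

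Median scaling gave 204 higher for Dex with LPS at 6 h, 75 higher for Dex at 3 h, 414 and 64 for Dex at 6 h, 266 and 26 for LPS at 3 h, a 6 h interaction of 91 and a 6 h share of 9.09%. It moved the median of all genes by 0.171 (LPS, 3 h), 0.137 (Dex, 3 h), 0.139 (LPS, 6 h), 0.284 (Dex, 6 h) and 0.142 (Dex with LPS, 6 h). The 6 h interaction was 73 at a detection p under 0.01, 83 with trend and robust fitting and 21 without a filter, where Dex at 3 h lowered 6. LPS-induced genes chosen in the other experiment gave shares of 12.2% at 3 h and 2.19% at 6 h, and in the same experiment 17.3% at 3 h. The added fit on LPS and Dex plus LPS means alone gave 58 higher and 145 lower (0 and 0 in the full fit), and fits on those 4 arrays gave 87 and 174 at 3 h and 111 and 199 at 6 h.

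Replicate numbers gave no sign of pairing the arrays: the correlation of deviations with the same number was -0.00031 to 0.0291 at 3 h and -0.220 to 0.00906 at 6 h, with 0 of 6 pairs over 0.1 in each. The -0.220 was that of the 6 h unstimulated and Dex arrays, so other structure between those arrays stays open. With the replicate number as a block the 6 h interaction was 16, and every other count of a single experiment stayed within 1.5 times.

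With each array left out, counts ranged over 88 to 101 higher and 181 to 196 lower (Dex with LPS, 3 h), 37 to 110 and 106 to 195 (6 h), 27 to 54 and 6 to 18 (Dex, 3 h), 77 to 283 and 92 to 321 (6 h), 159 to 189 and 67 to 95 (LPS, 3 h), and 626 to 698 and 660 to 726 (6 h). The interaction ranged over 658 to 697 (3 h) and 3 to 385 (6 h), the LPS difference over 1512 to 1651, the Dex difference over 229 to 497, the shares over 33.3% to 46.7% (3 h) and 10.0% to 16.7% (6 h), and all 6 counts of the fit on both experiments were 0 with limma (422, 191 and 691 at an unadjusted p under 0.05 with all arrays for Dex with LPS, Dex and LPS). Arrays that moved a count by over 1.5 times were, at 3 h, Dex replicate 1 (27 higher with Dex), Dex replicate 2 (6 lower) and unstimulated replicate 1 (the 6 h share, 10.0%). At 6 h they were Dex replicate 1 (77 and 92 with Dex, interaction 14) and replicate 2 (283 and 321, interaction 385, Dex difference 497), Dex plus LPS replicate 1 (45 and 107, interaction 3) and replicate 2 (37 and 106, interaction 6), LPS replicate 1 (60 and 119, interaction 4) and replicate 2 (54 and 112, interaction 7), and unstimulated replicates 1 and 2 (interaction 9 and 16). Named genes that lost a 6 h call without single arrays and are not given above included Per1 (1.49 to 1.88), Mmp8 (1.25 to 1.58), Il27 (-1.18 to -0.97), Cish (-1.17 to -0.90), Cxcl3 and Ciita (bounds only) for Dex with LPS, Mfge8 (-1.25 to -1.05), C1qc (0.95), Ccl9 (0.99), Cd86 (-0.96), Egr1 (-0.85), Ltf (-0.91), Mmp9 (-0.87), Nfkbib (-1.17 to -1.11) and Thbs1 (a bound only) for Dex, and Cd83 (0.85 to 0.98), H2-DMa (at most -0.98), Dcn (0.86 to 1.08), Cd200r1 (-1.16 to -0.83) and Ltf (-0.90 to -0.81) for LPS. Tarsl2 lost its 6 h call for LPS too (a bound only). At 3 h Csf2 (-1.26 to -0.64) lost its call for Dex with LPS.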

Other observations

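No explanation is tested in this part, and the lists were fixed before the data were examined. In the 6 h experiment 6 of 21 Toll-like receptor pathway genes rose with LPS, among them the kinase gene Irak2 (2.43 ± 0.22), Tlr1 (2.12 ± 0.21) and Tlr6 (1.72 ± 0.21), and Tlr13, a sensor of bacterial ribosomal RNA, fell (-1.45 ± 0.21; camera adjusted p = 0.00858, and adjusted p = 0.158 with an estimated correlation). With Dex added to LPS Tlr2 rose (1.00 ± 0.18), a call lost without any 1 of the 4 arrays compared (0.93 to 1.08). Of 17 cell cycle genes 6 fell with LPS at 6 h, among them Aurka (-1.79 ± 0.24), Mcm5 (-1.42 ± 0.23) and Mcm2 (at least 2.58-fold), while Ccne1, for cyclin E1, was at least 3.09-fold higher (adjusted p = 0.0187, and adjusted p = 0.172 with an estimated correlation). Ccne1 fell with Dex added to LPS at 3 h and 6 h (-1.76 ± 0.13 and -1.27 ± 0.24, the latter lost without Dex plus LPS replicate 1 or either LPS array, -1.32 to -0.96). Tk1, thymidine kinase, rose with Dex alone at 6 h (1.21 ± 0.20; adjusted p = 0.00937, and adjusted p = 0.165 with an estimated correlation). The hypoxia regulator gene Hif1a (1.47 ± 0.18), the lactate exporter gene Slc16a3 (1.09 ± 0.24) and Pdk1 (1.06 ± 0.24) rose with LPS at 6 h among 13 genes of glycolysis and hypoxia (adjusted p = 0.078), of which Pdk1 was lost without LPS replicate 2 or unstimulated replicate 1 (0.82 to 0.91) and Slc16a3 without LPS replicate 1 (0.96). Slc16a3 fell with Dex added to LPS at 3 h (-1.06 ± 0.20), a call lost without LPS replicate 1 or Dex plus LPS replicate 2 (adjusted p = 0.0136, and adjusted p = 0.172 with an estimated correlation).

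Of 12 genes of MHC class I and the immunoproteasome, Nlrc5, their transactivator gene, rose with LPS at 6 h (1.19 ± 0.17) as did Psmb8 (1.01 ± 0.29, lost without unstimulated replicate 2 or either LPS array, 0.52 to 1.05; adjusted p = 0.00807, and adjusted p = 0.266 with an estimated correlation). With Dex added to LPS, Nlrc5 fell at 3 h (-1.01 ± 0.08, lost without LPS replicate 1 or Dex plus LPS replicate 2, -0.98 to -0.94; adjusted p = 0.0453, and adjusted p = 0.223 with an estimated correlation). Tapbp and Psme2 fell at 6 h, both lost without any 1 of the 4 arrays compared (-1.23 to -0.79 and -1.12 to -0.90; adjusted p = 1.04e-04, and adjusted p = 0.172 with an estimated correlation). Of the lysosomal genes 16 were measured, and the acid lipase gene Lipa fell with LPS at 6 h (-1.46 ± 0.37, lost without LPS replicate 2 or unstimulated replicate 2, -1.14 to -1.04; adjusted p = 0.0887) and with Dex added to LPS at 3 h (-1.16 ± 0.09; adjusted p = 0.0374, and adjusted p = 0.197 with an estimated correlation). Among macrophage identity genes Fcgr1 fell with Dex added to LPS at both times (-1.18 ± 0.09 and -1.03 ± 0.22), the 6 h call being lost without LPS replicate 2 or either Dex plus LPS array (-1.21 to -0.80), and Trem2 fell with LPS at 6 h (-1.23 ± 0.17). Of 12 sterol genes limma called 0 with Dex added to LPS at 6 h (6 at an unadjusted p under 0.05, and 1 higher adjusted over the list alone; adjusted p = 0.00127, and adjusted p = 0.129 with an estimated correlation). Of 7 genes of the glucocorticoid receptor and its cofactors limma called 0 in every comparison (at an unadjusted p under 0.05, 3 for LPS, 2 for Dex and 4 for Dex with LPS at 3 h, and 3, 1 and 2 at 6 h).

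Between 3 h arrays labelled LPS and unstimulated, which carry the doubt about labels, the called list members not yet given were Jund (2.16 ± 0.11), Slc16a3 (1.78 ± 0.20), Dhcr7 (1.53 ± 0.14), Spi1 (1.23 ± 0.09), Oas3 (1.16 ± 0.07), Cd200r1 (at least 1.98-fold) and Tap2 (-1.04 ± 0.10). Of these calls that of Cd200r1 was lost without any 1 of the 4 arrays compared and that of Tap2 without LPS replicate 1 or unstimulated replicate 2 (-0.96 to -0.94). Between those labelled Dex and unstimulated they were Jund (1.41 ± 0.11), Slc16a3 (1.16 ± 0.20) and Dhcr7 (1.11 ± 0.14), the last 2 lost without unstimulated replicate 2 (0.89 and 0.99). Lists with a camera adjusted p under 0.05 there were NF-kB regulators, interferon-stimulated genes and macrophage identity for LPS (0.0134, 0.0453 and 0.00638, and adjusted p = 0.167, 0.194 and 0.324 with an estimated correlation) and macrophage identity for Dex (0.0374, and adjusted p = 0.401 with an estimated correlation).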
